A study of Mus musculus with 8 samples.

How the data were processed

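Bulk RNA sequencing was analysed from the calvaria, the flat bones of the skull roof, of newborn female C57BL6 mice aged 2 to 3 days. The 8 libraries came from 4 wild-type mice and 4 mice lacking Girk3, the potassium channel subunit encoded by Kcnj9. Per the labels' protocols, the tissue was frozen, RNA was taken up in Trizol and purified on columns, and libraries were made with the NEBNext Ultra II RNA kit. Groups and replicate numbers were taken from the sample titles.

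The deposited table holds raw counts per Ensembl gene ID for each library, with 49315 gene IDs and no normalization by the authors. Per the submitters' processing notes, the tools were bcl2fastq 2.17, STAR 2.5.2b and featureCounts from Subread 1.5.2, with the mouse build mm10. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may not be separable. Symbols were found for 48970 IDs. Coordinates were taken from GENCODE mouse release 21, which is on the same build (GRCm38/mm10), for 49056 IDs; the other 259 IDs had none.

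Genes were kept with the default filter of edgeR's filterByExpr (minimum count 10, minimum total count 15), which left 17743 genes holding 99.9% of the counts. Library sizes were scaled with TMM factors, which ran from 0.972 to 1.04. Wild-type and knockout libraries were compared with the quasi-likelihood test of edgeR 4.0.16 (robust shrinkage, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are knockout over wild type on the log2 scale with standard errors from the fit. Counts of tested genes in single libraries were scaled to library totals multiplied by the TMM factors (CPM), and log2 CPM used a prior count of 2. The CPM given for Kcnj9, Kcnj3 and the channel and receptor genes below the filter used library totals alone. A gene below the filter was compared by an exact permutation test of CPM, two-sided, whose smallest possible p with 4 libraries against 4 is 0.0286.

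Before the data were examined, 41 gene lists were fixed for bone cells, signalling pathways, blood and immune cells and tissues that dissection can carry along. The 40 lists with at least 3 tested members were tested with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera with an estimated correlation and the rotation test fry were run beside it. The share of called genes within 5 Mb of Kcnj9 was compared with the share elsewhere by Fisher's exact test. Principal components were computed from log2 CPM of the tested genes.

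The named genes followed a rule fixed at the same time. It took Kcnj9, then the 12 genes of smallest p in each direction whose 4 knockout libraries all lay on one side of the 4 wild-type libraries. These had a mean of at least 1 CPM in the higher group and a symbol that is not a clone or model number. It also took up to 4 members of smallest p in each list described, and a fixed set of bone, osteoclast, channel and receptor genes whatever their values.

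Library totals ran from 35.4 M to 54.3 M counts, so 1 count was at most 0.0283 CPM. The floor of 3 counts was at most 0.0848 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The test was tried on counts simulated from the means and library sizes of these samples. It recovered 31 of 65 genes changed 1.5-fold, 42 of 66 changed 2-fold and 56 of 62 changed 4-fold, with 9 false calls (6.12% of calls) over 17481 genes.

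Alternatives covered other normalizations, filters and thresholds, DESeq2 1.42.0, limma-voom, a surrogate variable from sva 3.50.0, covariates for tissue carried along, the replicate number as a block, and leaving out each library. Figures were drawn with matplotlib 3.10.9. No sample was left out of the comparison. The p-values of single genes and of exact permutation tests over libraries measure the spread between these 8 samples. Those of Fisher's exact tests and of permutation tests over genes do not, since they treat genes as the units. Camera with the preset correlation sets genes against genes, so its p-values are not a measure of that spread either.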

Results

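Gene expression was measured in newborn calvaria of 4 wild-type and 4 Girk3 knockout female mice, each library from a separate sample. Totals were 45.6 M ± 2.89 M counts in wild type and 45.1 M ± 7.92 M in knockout (mean ± SD, n = 4 each), and ran from 35.4 M to 54.3 M. The study concerns bone mass after loss of Girk3, a subunit of the G protein-gated inwardly rectifying potassium channels, and the comparison asks which transcripts differ between the genotypes in bone.

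Kcnj9 (ENSMUSG00000038026, chromosome 1 from 172320501 to 172329318, minus strand, GRCm38/mm10) was close to the counting floor in every library. The wild-type libraries held 0, 0, 1 and 4 counts, and the knockout libraries 2, 5, 7 and 9. The means were 0.0257 ± 0.0381 CPM in wild type and 0.138 ± 0.092 CPM in knockout (SD, n = 4 each; exact permutation p = 0.0571). Counts were therefore not lower in the libraries labelled knockout, and at this depth the gene does not check the labels. The Kcnj9 level stayed higher in knockout whichever library was left out. The largest difference, 0.144 CPM (exact permutation p = 0.0286), came without knockout replicate 1, which held the fewest counts of the knockout libraries, at 2. With all libraries the permutation p was 0.4 when adjusted over the channel and receptor genes named here, so a rise is not shown. Knockout below means the libraries labelled so. Of the other channel and receptor genes, Kcnj5, Kcnj6 and Oprk1 also failed the count filter, with at most 18, 5 and 2 counts in any library. So did Oprm1 and Oprd1, named after their values were seen: Oprm1 held 12 counts in 1 knockout library and 0 in the other libraries, and Oprd1 at most 4 in any library. Kcnj3 passed it and held 0.202 ± 0.0908 CPM in wild type and 0.226 ± 0.172 CPM in knockout (SD, n = 4 each; exact permutation p = 0.857).

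The genes of smallest p included transcription factor, MAP kinase phosphatase and lysozyme genes that fell in knockout and a secreted antagonist gene that rose. Fos, a transcription factor gene induced within minutes of many stimuli, was at 18.9 ± 0.527 CPM in knockout against 51 ± 13.8 CPM in wild type (SD, n = 4 each), and its partner Jun at 34.4 ± 5.15 against 70.6 ± 5.34 CPM. Dusp8, a phosphatase acting on MAP kinases, fell by 1.36 ± 0.0888 on the log2 scale (SE, adjusted p = 2.12e-05), and Lyz2, the lysozyme of macrophages and neutrophils, fell by 0.89 ± 0.0811 (adjusted p = 0.000487). In the other direction Ifi202b, an interferon-inducible gene of the Ifi200 family, was 14.6-fold higher in knockout, at 13.7 ± 2.42 against 0.936 ± 0.264 CPM (adjusted p = 3.94e-06). Dkk1, a secreted Wnt antagonist, rose 1.46-fold (adjusted p = 0.0124).

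**Figure D1:**
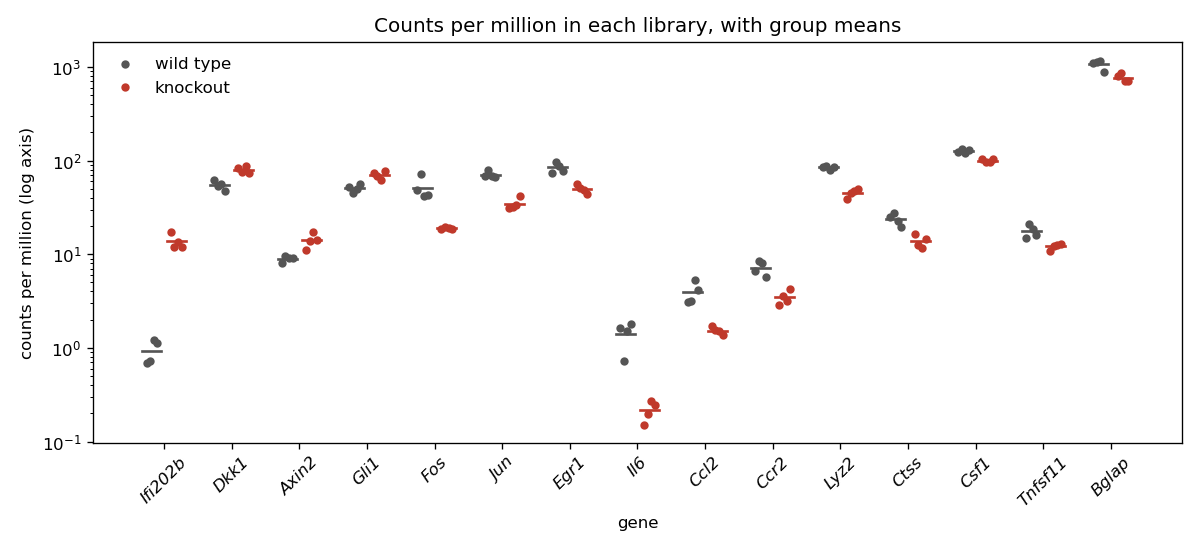
CPM (log axis) of 15 named genes in each of the 4 wild-type (grey) and 4 knockout (red) libraries, with a bar at each group mean. Fos lies near 51 CPM in wild type and 18.9 CPM in knockout, and Ifi202b near 0.936 and 13.7 CPM.

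Among 17743 tested genes, 234 differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 79 higher and 155 lower in knockout, and 44 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 3087. Of the 234 calls, 66.2% were lower, and most alternative settings kept a majority lower. The share was 46.7% with library totals in place of TMM factors, 48.4% with the skin covariate and 49.8% without knockout replicate 4. In 1879 genes (10.6%) the groups did not overlap, against 2.86% by chance. Other genes of small p that rose included Tob2, Atg9b, Bcl7a, Camk1d, Bsn, Sema6a, Fgfbp3, Amt and the small nucleolar RNA Snord123, by 0.46 to 1.05 on the log2 scale. The calls of Camk1d, Bsn, Sema6a, Fgfbp3, Amt and Snord123 were each lost without at least 2 of wild-type replicates 2, 3 and 4 and knockout replicates 1, 2 and 3, with adjusted p up to 0.0841. Those that fell included Dusp23, Ccn2, Nfatc2, Bhlhe40, Ccn1, Tbc1d13 and Nnt, with log2 changes from -1.36 to -0.61. Reads of Ifi202b may be shared with related Ifi200 genes, and 23.2% of the exon bases of Ccn2, 7.45% of those of Atg9b and 7.28% of those of Jun overlap an annotated gene on the opposite strand, so these values are less certain.

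The number of differentially expressed genes depended on single libraries. It was 79, 75 and 105 without wild-type replicates 2, 3 and 4, and 57 and 82 without knockout replicates 2 and 3. Without knockout replicate 4 it was 608. Among 54 called genes followed by name, 30 stayed called whichever library was left out. Non-coding genes made up 26 of the 79 higher calls (32.9%) and 5 of the 155 lower calls (3.23%; Fisher's exact p = 9.13e-10). The share of counts in intronic and unconfirmed gene models moved with genotype as well, at 0.0812 ± 0.0032% in wild type and 0.105 ± 0.0118% in knockout (SD, n = 4 each; exact permutation p = 0.0286, the smallest the design allows).

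Among genes of bone-forming cells, 2 osteoblast genes passed the test and no osteocyte gene did. Of 30 osteoblast and bone matrix genes, 2 fell and none rose: Mmp13, a collagenase, by 0.97 ± 0.149 on the log2 scale (SE, adjusted p = 0.0135), and Bglap, which encodes osteocalcin, by 0.48 ± 0.101 (adjusted p = 0.0383). Adjusted over the list alone, 3 fell. At an unadjusted p under 0.05 there were 10 of the 30 (6 of them lower), against 3087 of all 17743 tested genes. DESeq2 called 3 lower and limma-voom 1 lower. Over all tested genes 1.32% were called in edgeR, so 2 of 30 is not a smaller share than elsewhere. The list as a whole did not move in 1 direction against other genes (camera adjusted p = 0.896), but it passed with both directions counted (fry mixed adjusted p = 4.68e-05). The latter test asks whether any members changed and does not say how many. Runx2 (log2 change 0.10 ± 0.106, adjusted p = 0.674), Sp7 (0.12 ± 0.069, 0.391), Alpl (-0.09 ± 0.0842, 0.602), Col1a1 (-0.12 ± 0.116, 0.625) and Ibsp (-0.25 ± 0.102, 0.244) did not pass. None of the 14 osteocyte genes passed in edgeR (4 at an unadjusted p under 0.05, 2 in DESeq2, 0 in limma-voom), with Sost at 0.57 ± 0.173 (adjusted p = 0.148) and Dmp1 at -0.07 ± 0.118 (0.802). The Bglap call was lost without any 1 of replicates 1, 2 and 3 of either group, with adjusted p from 0.0187 to 0.127 over all left-out libraries, and its reads can be shared with the near-identical Bglap2. The Mmp13 call was lost without wild-type replicate 4 or knockout replicates 2 or 3, with adjusted p up to 0.0564.

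Macrophage genes were lower in knockout. Of 26 macrophage and monocyte genes, 8 fell, none rose and 25 had a log2 change below 0 (median -0.47, camera adjusted p = 1.17e-15); adjusted over the list alone, 20 fell. The call was lost at adjusted p = 0.0651 with an estimated correlation. Besides Lyz2, the chemokine receptors Ccr2 and Cx3cr1 fell by 1.05 ± 0.168 and 0.72 ± 0.111 on the log2 scale, and the lysosomal protease Ctss fell by 0.78 ± 0.126 (SE). The Ctss call was lost without knockout replicate 2 (adjusted p = 0.0559). Fcer1g, named after its value was seen, was also among the 8 and fell by 0.38 ± 0.0758 (SE, edgeR adjusted p = 0.0316). It lies within 5 Mb of Kcnj9 and is counted among the called genes of that region as well. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, chosen after their values were seen, had log2 changes of -0.61, -1.02, -0.72 and -0.53 and did not pass in edgeR. Across the whole lists, 17 of 25 erythroid genes (median 0.22) and 15 of 19 B cell genes (median 0.27) had a log2 change above 0. None of either list was called in edgeR, while DESeq2 called 1 erythroid gene, lower in knockout, and no B cell gene. Of 22 osteoclast genes, none passed over all genes in edgeR (16 at an unadjusted p under 0.05, 10 in DESeq2, 0 in limma-voom), 21 had a log2 change below 0 (median -0.42) and 15 fell adjusted over the list alone. Camera gave adjusted p = 6.56e-10 for this list, and adjusted p = 0.383 with an estimated correlation. Acp5 (-0.51 ± 0.162, adjusted p = 0.156) and Ctsk (-0.40 ± 0.153, 0.21), both abundant osteoclast enzymes, did not pass.

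Of 18 genes through which stromal cells regulate osteoclasts, 5 fell and none rose over all genes, and 5 fell adjusted over the list alone (camera adjusted p = 0.00132, and adjusted p = 0.0651 with an estimated correlation). Besides Il6 and Ccl2, given below, and Ptgs2, named here after its value was seen, they were Csf1, a macrophage growth factor, by 0.35 ± 0.0633 on the log2 scale (SE, adjusted p = 0.0223), and Tnfsf11, which encodes RANKL, by 0.54 ± 0.112 (adjusted p = 0.0361). The decoy receptor gene Tnfrsf11b was at 0.26 ± 0.14 (adjusted p = 0.37). The Tnfsf11 call was lost without any 1 of wild-type replicates 2, 3 and 4 and knockout replicates 1, 2 and 3 (adjusted p 0.021 to 0.12). The Csf1 call was lost without any 1 of the same libraries except knockout replicate 1 (0.0169 to 0.0923).

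Of 25 immediate early and heat shock genes, 11 fell and none rose (median log2 change -0.48, camera adjusted p = 9.11e-15, and adjusted p = 0.0513 with an estimated correlation). Adjusted over the list alone, 15 fell and 1 rose. Jun, Ccn1, Fos and Ier3 led it, with log2 changes of -1.04, -0.82, -1.43 and -1.06. Of 24 inflammatory cytokine and chemokine genes, 7 fell and none rose, and 14 fell adjusted over the list alone (camera adjusted p = 1.45e-10, and adjusted p = 0.0766 with an estimated correlation). Il6 fell by 2.71 ± 0.346 on the log2 scale from a low level of 1.41 ± 0.476 CPM (SD, n = 4), and the monocyte chemokine genes Ccl2 and Ccl7 fell to 0.391 and 0.355 of their wild-type levels. The Ccl7 call was lost without knockout replicate 2 (adjusted p = 0.0553).

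Genes of the Wnt pathway moved both ways. Of 24 Wnt target and antagonist genes, 2 rose (Dkk1 and Axin2) and 1 fell, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0086, and adjusted p = 0.0831 with an estimated correlation). Axin2, a feedback inhibitor that Wnt signalling induces, rose by 0.66 ± 0.12 on the log2 scale (SE, adjusted p = 0.0231), whereas the antagonist gene Sfrp4 fell by 0.97 ± 0.142 (adjusted p = 0.012). In the BMP and TGF-beta list 3 of 29 genes rose and 3 fell, and 7 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.946). Among them Smad9 rose and Ccn2 fell, and, named after their values were seen, Bmp4 rose and Gdf10 fell. Among 30 suture and calvarial mesenchyme genes, Gli1 and Zic1 rose by 0.47 ± 0.0871 and 0.49 ± 0.0974 (camera adjusted p = 0.201); adjusted over the list alone, 4 rose and 1 fell. The Dkk1 call was lost without wild-type replicate 2 (adjusted p = 0.0509). Wild-type replicates 2 and 3 and knockout replicate 2 each ended the calls of Axin2, Smad9, Zic1 and Gli1 when left out, with adjusted p up to 0.0719, 0.0828, 0.113 and 0.0841. So did wild-type replicate 4 for all but Gli1, wild-type replicate 1 for Axin2 and Zic1, knockout replicate 1 for all but Axin2, and knockout replicate 3 for Axin2 and Smad9.

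Camera with the preset correlation called 18 of the 40 lists, and none with an estimated correlation (9 at an unadjusted p under 0.05), while fry called 9 in 1 direction and 20 with both directions counted. In 5 lists that were not called, neutrophil, erythroid, cartilage, tendon and the unfolded protein response, the median, the mean and the test did not share 1 sign. Among the 35 ways to split these 8 libraries into 4 and 4, 6 gave at least 18 called lists, the real one included, and 16 gave at least 1 list a camera p as small as that of the immediate early list.

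**Figure D2:**
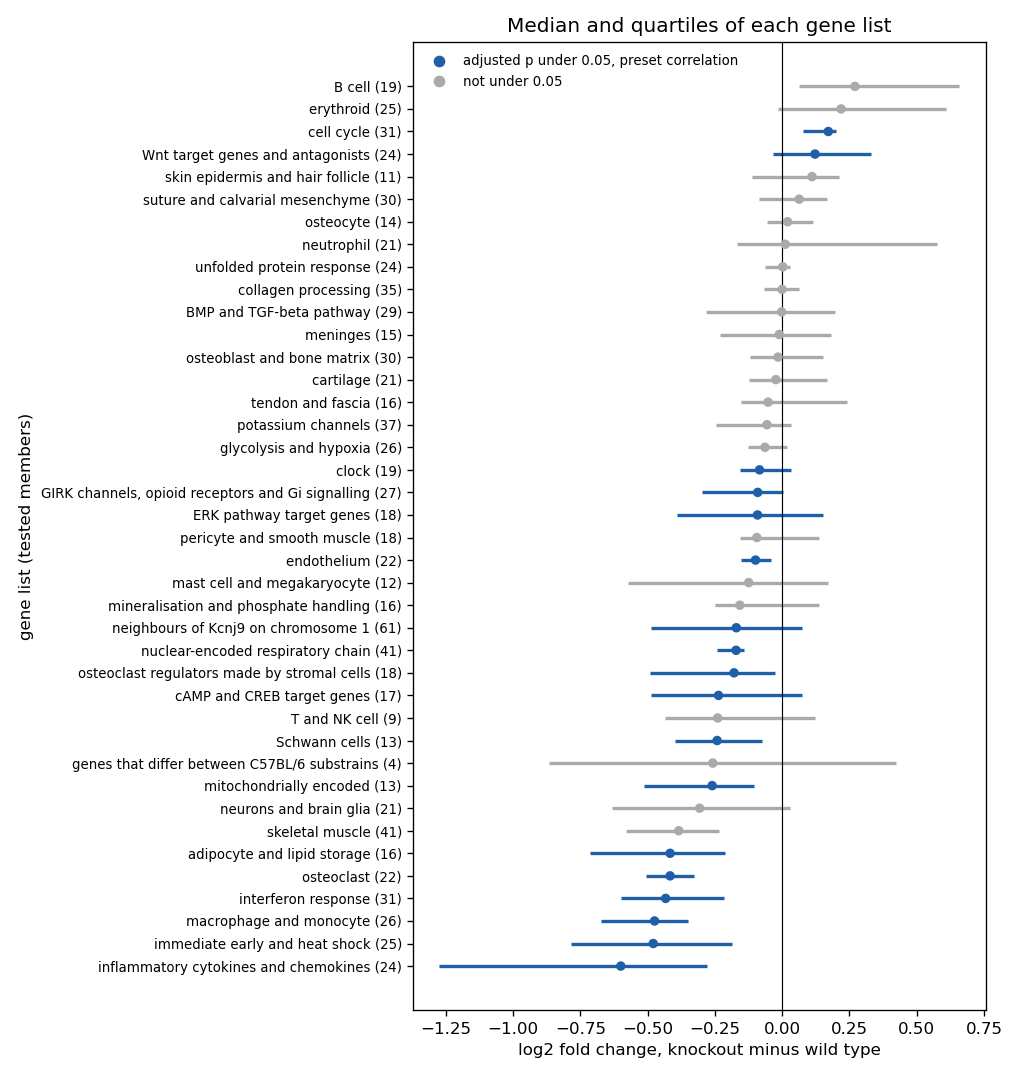
Median (point) and quartiles (line) of log2 fold change, knockout minus wild type, over the tested members of each of 40 gene lists, with the number of tested members in brackets; blue marks the 18 lists called with the preset correlation. The macrophage and monocyte list has a median of -0.47 and the osteoblast and bone matrix list a median of -0.02.

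Called genes were concentrated near Kcnj9 on chromosome 1. Within 5 Mb either side, 15 of 109 tested genes were called (13.8%), against 219 of 17634 elsewhere (1.24%; odds ratio 12.7, 95% interval 6.72 to 22.5, Fisher's exact p = 1.37e-11). Of the 15, 12 were lower and 3 higher in knockout. The phosphatase gene Dusp23 (172630764 to 172632962) fell by 1.36 ± 0.118 on the log2 scale, the lymphocyte surface gene Cd48 (171682009 to 171705258) by 1.28 ± 0.159 and Cfap126 (171113918 to 171126967) by 1.75 ± 0.252 (SE). Ncstn, a gamma-secretase subunit gene, fell by 0.41 ± 0.059; 4.91% of its exon bases overlap Copa on the opposite strand, which held 493 CPM in wild type and 414 CPM in knockout, so its value is less certain. Ifi202b (173962568 to 173982744) and the gene model Gm20045, named after its value was seen, were among those that rose. For genes near Kcnj9 the odds ratio was 21.8, 26.8 and 22.9 without wild-type replicates 2, 3 and 4, and 36.5, 26.6 and 5.95 without knockout replicates 2, 3 and 4.

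**Figure D3:**
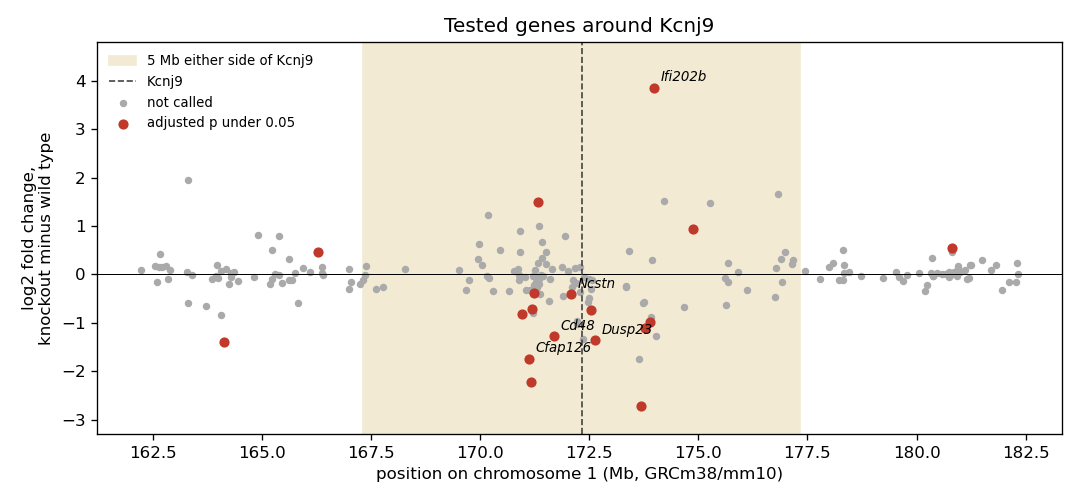
Log2 fold change, knockout minus wild type, of tested genes within 10 Mb of Kcnj9 against position on chromosome 1 (Mb, GRCm38/mm10); red points are called genes and the shaded band spans 5 Mb either side of Kcnj9 (dashed line). Of the 109 genes in the band, 15 were called.

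Skeletal muscle RNA differed widely between libraries. The mean log2 CPM of 41 muscle genes was -1.10 in wild-type replicate 3 and 0.26 and 1.30 in knockout replicates 2 and 3, against 3.16 to 4.82 in the other 5 libraries. It did not separate the genotypes (2.87 ± 2.65 in wild type and 2.38 ± 2.01 in knockout, SD, n = 4 each; exact permutation p = 0.83). The first principal component held 38.9% of the variance and set these 3 libraries apart; the second, with 16.8%, set knockout apart from wild type. Without these 3 libraries, a choice made after seeing the data, 3 wild-type and 2 knockout libraries remained and 8 differentially expressed genes were called, 7 of them among the 234. Knockout replicate 4 had reads in 28520 genes, against 24545 to 25729 in the others, at the lowest total of 35.4 M counts.

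**Figure D4:**
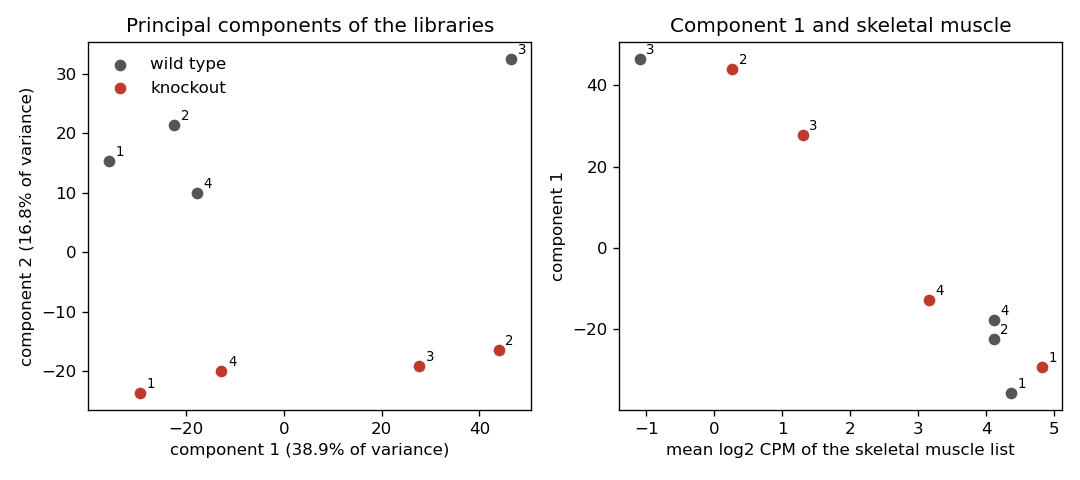
Left, the first and second principal components of log2 CPM for the 4 wild-type (grey) and 4 knockout (red) libraries, numbered by replicate. Right, the first component against the mean log2 CPM of the skeletal muscle list; wild-type replicate 3 and knockout replicates 2 and 3 lie at -1.10, 0.26 and 1.30.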

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

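The tests below of mapping loss near Kcnj9, of immediate early against macrophage genes, of list scores between libraries, of the genes of smallest p near Kcnj9, of any list in the splits and of shares of counts were chosen after all or part of their result was seen. Of the others, the split test for called genes and the odds ratio near Kcnj9 were set before any comparison of the genotypes; the rest were set after a first comparison had been seen, though before their own values were.

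In groups of 4 libraries, 7 of 158 groups held a library far from the other 3, where chance alone gives about 7.9. Jun was at 78.6 CPM in wild-type replicate 2, against 66.8 to 68.8 in the others. Nnt was at 33.1 CPM in knockout replicate 4 and Tnfsf11 at 10.8 CPM in knockout replicate 1. The mean log2 CPM of the stromal osteoclast regulators was 4.13 in wild-type replicate 2, and that of the clock list was 3.93 in knockout replicate 3. The unfolded protein response list stood at 6.38 in knockout replicate 2. The skeletal muscle list was at -1.10 in wild-type replicate 3, against 4.11 to 4.36 in the others. Y-linked genes, which no comparison used, held 11 counts in wild-type replicate 1 and 5 in wild-type replicate 4, above the floor of 3 counts.

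In 1 of 35 splits, the real one, 15 genes near Kcnj9 were called and the highest other gave 0, but 33 of the 34 other splits called no gene anywhere, so that count decides nothing about the region. Among the 234 genes of smallest p in each split, the real one placed 15 near Kcnj9 and the highest other 8 (1 of 35 as many). Chance is therefore unlikely, though 1 of 35 is the smallest share the design allows. A stretch of donor-strain chromosome retained around the targeted gene would give an odds ratio above 1, as the value of 12.7 is. No size was predicted, and an effect of Kcnj9 loss on its neighbours could give an excess as well. The donor-strain explanation may account for Ifi202b and Dusp23. Of the calls near Kcnj9 80% were lower in knockout, against 65.3% elsewhere (Fisher's exact p = 0.397), so reads of a donor strain mapping less well to the reference stay open for the lower genes. An effect of Kcnj9 loss on its neighbours was not tested and also stays open.

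For the immediate early list taken alone 1 of 35 splits, the real one, gave a camera p as small (4.56e-16; the next was 5.88e-08), but in 16 of 35 splits some list reached a p as small (smallest 2.90e-65), so for a list picked among 40 chance cannot be excluded. A stress of heat-shock type during handling of wild-type tissue would lower the heat shock genes in knockout; their median log2 change was -0.19, between the bounds set, and none of the 5 passed. Fewer macrophages could carry fewer immediate early transcripts: the immediate early median lay below that of the macrophage list by a difference of -0.16 (permutation p = 0.186, genes not being independent), which does not decide. Handling of another kind and an effect of genotype both stay open, and the shares of counts in protein-coding genes (98.3 against 98.1% in knockout), lincRNA (0.964 against 1.07%), antisense (0.144 against 0.169%) and intronic models (0.0812 against 0.105%) also separated the genotypes (exact permutation p = 0.0286 each).

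Of 26 macrophage genes 8 fell in edgeR over all genes, while none of 22 osteoclast genes passed. DESeq2 called 16 and 10 of them lower. Among the 8 macrophage calls in edgeR, Fcer1g lies within 5 Mb of Kcnj9 and so counts in both patterns. Less marrow or blood in the knockout tissue stays open: the neutrophil median lay 0.49 above the macrophage median on the log2 scale (permutation p = 2e-05 over genes), which had been set to count against it, but that test ignores the spread between libraries, where the neutrophil minus macrophage score differed by 0.23 (exact permutation p = 0.857). That score rests on single libraries, with differences of 0.36 and 0.044 without wild-type replicates 2 and 4 and of 0.90 (exact permutation p = 0.0857), -0.14 and -0.030 without knockout replicates 1, 2 and 3. With the muscle score as a covariate 104% of the macrophage median was kept, which tests little since that score did not separate the genotypes, but dilution by muscle would lower osteoblast genes alike, and the macrophage minus osteoblast score differed by -0.44 (exact permutation p = 0.0286; 0.0571 without any 1 wild-type library), whereas the osteoclast minus osteoblast score, at -0.35 (exact permutation p = 0.114; 0.0286 without wild-type replicate 1), leaves it open for osteoclast genes. A lower number of macrophages and lower expression per cell were not tested and stay open.

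The number of called genes exceeded that of the other splits: 1 of 35, the real one, gave 234, and the highest other gave 22. Chance is therefore unlikely, though 1 of 35 is the smallest share the design allows. For the number of called lists chance is not excluded, since 6 of 35 splits gave at least the real 18 and the highest other gave 24.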

How the results depend on the processing

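The removal of the 3 libraries low in muscle, library totals for the lists and TMM factors for Kcnj9 were chosen after seeing the data. There were 234 differentially expressed genes, with 79 among the differentially expressed genes, higher in knockout and 155 among the differentially expressed genes, lower in knockout; pairs in brackets keep this order. DESeq2 gave 969 (373, 596), the skin covariate 905 (467, 438), no filter 355 with 248 lower, and an adjusted p under 0.1 gave 572 (219, 353). A 2-fold minimum left 44 (19, 25) and glmTreat against 1.2-fold 41 (9, 32). Library totals alone left 99 lower, limma-voom 51 higher, and 1 surrogate variable gave 233 lower. Without the 3 low-muscle libraries 8 remained (2, 6), with 5 libraries left. Leaving out single libraries gave 57 to 608 calls, 16 to 305 higher and 41 to 303 lower. Lower genes were 66.2% of calls with TMM factors and 46.7% with library totals, which moved the median of all genes to 0.05. Apart from smaller sample numbers and stricter or looser thresholds, the cause was not tested. Of 54 called genes followed by name across 22 settings, 4, Ifi202b, Dusp8, Dusp23 and Lyz2, kept their call, and 26 more lost it only without the 3 low-muscle libraries.

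With the replicate number as a block, 126 genes were called, 22 of them higher, and 96 were among the 234. Same-numbered libraries did not deviate together as a set (correlations 0.255, -0.179, 0.34 and -0.005). The values give no sign that the numbers pair the samples, but cannot exclude it. Differently numbered libraries reached 0.556, for wild-type replicate 3 and knockout replicate 2, both low in skeletal muscle. With the block 18 lists were called, and for genes near Kcnj9 the odds ratio was 20.98.

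The Kcnj9 level stayed higher in knockout under the settings run, from 0.0729 to 0.144 CPM with single libraries left out (exact permutation p 0.0286 to 0.143) and 0.112 CPM with the block (p = 0.125). The gene fails the filter, so covariate and voom settings gave no value; without a filter its adjusted p was 0.396. With an estimated correlation 0 lists were called, and with fry 9. Estimated correlations gave adjusted p = 0.383 (osteoclast; 0.115 by fry), 0.0651 (macrophage, stromal regulators, Kcnj9 neighbours), 0.0831 (Wnt), 0.0513 (immediate early) and 0.0766 (inflammatory). Fry gave adjusted p = 0.00312 (macrophage), 0.000777 (stromal regulators), 0.00141 (Kcnj9 neighbours), 0.0118 (Wnt), 0.000648 (immediate early) and 0.00697 (inflammatory). Single libraries left out gave 15 to 23 called lists. Directions turned without wild-type replicate 1 for the adjusted p of the list neurons and brain glia (0.0212; with single libraries left out 0.0212 to 0.91), and without knockout replicate 1 for the adjusted p of the list neutrophil (0.0484; range 0.00162 to 0.379). They turned without the low-muscle libraries for the adjusted p of the list meninges (0.0434), the adjusted p of the list B cell (0.0118) and the adjusted p of the list cell cycle (0.586). There the log2 fold change of Runx2 turned to -0.037 and the log2 fold change of Dmp1 to 0.036; single libraries left out gave -0.14 to 0.028 for Dmp1. For genes near Kcnj9 the odds ratio passed in every setting, from 5.95 to 36.5 with single libraries left out. The first component held 66.8% over the most variable genes and 27.4% with genes scaled. At this depth, changes of 1.5-fold were recovered for 47.7% of simulated genes.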

Other observations

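The removal of 3 libraries low in skeletal muscle was chosen after the result was seen. Of 41 nuclear-encoded respiratory chain genes, 40 had a log2 change below 0 (median -0.17) and none passed over all genes in edgeR (14 at an unadjusted p under 0.05, 5 in DESeq2, 0 in limma-voom; camera adjusted p = 6.56e-10, and adjusted p = 0.643 with an estimated correlation). Of 31 cell cycle genes, 28 had a log2 change above 0 (median 0.17) and none passed (7 at an unadjusted p under 0.05, 2 in DESeq2; camera adjusted p = 4.2e-05, and adjusted p = 0.684 with an estimated correlation). Without the 3 low-muscle libraries the direction turned, and the adjusted p of the list cell cycle was 0.586. Of 31 interferon response genes none passed and 28 had a log2 change below 0 (median -0.43, 9 at an unadjusted p under 0.05, 2 in DESeq2; camera adjusted p = 3.09e-05, and adjusted p = 0.684 with an estimated correlation). In the Schwann cell list the myelin gene Mbp fell by 0.74 on the log2 scale (camera adjusted p = 0.00677, and adjusted p = 0.309 with an estimated correlation). The Mbp call was lost without knockout replicate 2 (adjusted p = 0.0553).

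Among signalling groups, 3 of 17 cAMP and CREB target genes fell, Fos, Dusp1 and Nr4a1, and none rose (7 fell adjusted over the list alone; camera adjusted p = 7.79e-05, and adjusted p = 0.0651 with an estimated correlation). These 3 genes are also members of the immediate early and heat shock list. The Nr4a1 call was lost without knockout replicate 2 (adjusted p = 0.0523). Of 27 genes of GIRK channels, opioid receptors and Gi signalling, 1 fell: Rgs10, a regulator of G protein signalling, by 0.50 on the log2 scale (camera adjusted p = 0.0074, and adjusted p = 0.0831 with an estimated correlation). The Rgs10 call was lost without any 1 of wild-type replicates 2, 3 and 4 and knockout replicates 1 and 2 (adjusted p up to 0.105).

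Genes that differ between C57BL/6 substrains were also followed; the substrain of either group and the number of backcrosses are not known from the labels. Nnt, a mitochondrial transhydrogenase gene disrupted in C57BL/6J, was at 37.1 ± 2.69 CPM in knockout and 67.5 ± 10.3 CPM in wild type (SD, n = 4 each; edgeR adjusted p = 0.00317). Wdfy1 was at a log2 change of -0.88 ± 0.183 (adjusted p = 0.056), Ide at 0.35 ± 0.086 (adjusted p = 0.0744) and Entpd4 at 0.65 ± 0.47 (adjusted p = 0.497). Of the 4 genes, 1 rose and 2 fell adjusted over the list alone, and DESeq2 called 1 higher and 2 lower. Whether the groups differ in substrain was not tested and stays open, also for called genes away from Kcnj9.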
